A study of Mus musculus with 2 samples.

How the data were processed

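Per the labels' protocols, the lungs of 3 chimeric mice were dissociated and pooled, live single cells were sorted as CD45-negative cells with and without tdTomato, and each sort gave 1 library on the 10x Genomics platform. The deposited values are raw UMI counts per gene and cell barcode, which the authors made with Cell Ranger as filtered matrices of called cells on the mm10 genome. The matrix headers and the submitters' processing notes give Cell Ranger 4.0.0, whereas the labels' protocol gives 3.0.1. That protocol also describes Seurat 3.1.1 for log-normalization and integration of 3 datasets on 2000 anchor genes and monocle3 0.2.0 for clustering. The integrated values, the authors' cell labels and the remaining dataset were not used here. Each matrix held 32285 genes, and the smallest barcode had 500 UMIs in the donor library and 505 in the recipient library. Of the gene symbols, 38 had more than 1 gene identifier and were kept apart by identifier. Positions came from GENCODE M21 (GRCm38, the same build as mm10), matched by gene identifier.

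The protocol states a filter on outliers of each dataset without its limits, so barcodes more than 3 scaled median absolute deviations from their own library's median were left out. In the donor library this kept barcodes with 691 to 7888 genes, at most 6.68% mitochondrial UMIs and at most 36143 UMIs, and left out 1332 of 6319, of which 954 had too few genes and 523 too high a mitochondrial share. In the recipient library the limits were 802 to 7423 genes, 7.35% and 31040 UMIs, and 473 of 3784 barcodes were left out, 283 and 297 for those reasons. Doublets were scored with Scrublet as in scanpy 1.11.5. Its automatic threshold marked 2 donor-library barcodes (0.0317%) and 7 recipient-library barcodes (0.185%), which was taken as a failed call. The highest scores were removed instead, at a rate of 0.8% per 1000 barcodes, that is 5.06% and 3.03%, which took 284 and 102 of the cells that had passed the filter. This left 4703 donor-library cells with a median of 6015 UMIs and 3209 recipient-library cells with a median of 6374.

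Cells were log-normalized to 10000 UMIs and integrated by anchors on 2000 variable genes and 30 components with Seurat 5.3.0 in R 4.3.3. A graph of shared nearest neighbours (20 neighbours, exact search in scikit-learn 1.9.0) was clustered with leidenalg 0.10.2 on igraph 0.11.9 at resolution 1. Clusters with epithelial markers were pooled and clustered again on 1000 genes and 15 components of the merged values. Of the 27 clusters, each was named after the fixed marker set with the highest mean log2 fold over the other cells. It needed a score of at least 0.75, at least 3 detected markers 2-fold over the rest, and no more markers of another class than of its own among its 10 leading genes. Clusters far shallower than their library's median also needed a marker of their own among those 10 genes. The score limit was set after the clusters had been seen, while marker sets, gene lists, the naming rule for genes and all alternative settings but 2 were fixed before the data were examined. Cell types were compared between the libraries where each library had at least 50 cells and no cluster of the type was led by another type's markers, which left 5 types. Alveolar type 2-like cells were too few in both libraries.

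With 1 library per group there was no test, and no p-value was computed. Shares carry exact (Clopper-Pearson) 95% binomial intervals, levels carry exact Poisson intervals, and ratios carry exact conditional intervals, all for counting error only. UMIs were summed per library and cell type, scaled to CPM of that sum, and compared as the log2 ratio of donor over recipient. Where 1 library had 0 counts, the ratio was computed with a floor of 3 counts over the group in place of 0. For each of 30 fixed gene lists the median log2 ratio was taken over members with at least 20 counts in both libraries together and at least 1 in each. It was set against 10000 random lists of the same size matched on expression in 20 bins, and lists with fewer than 3 such members gave no median. The percentile is a description of these 2 libraries and not a test. Intervals of list medians came from 200 Poisson redraws of the counts. Members were counted as higher or lower when at least 1.5-fold apart with an interval that excluded equality.

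Genes were named in a cell type when they reached 50 CPM in the higher library, differed at least 2-fold with an interval that excluded 1.5-fold, and stood at 20% or more of their level in any other compared type of that library. Mitochondrial, ribosomal protein, haemoglobin, sex-linked and unnamed gene models were left out. Of the rest, the 10 largest ratios each way were named in general capillary-like cells, up to 5 in aerocyte-like cells and up to 3 in the smaller types. Of these genes, 1 is not reported here. List members that met the level and ratio rule were named too, as were up to 10 genes each way that were 2-fold apart in at least 4 of the 5 types. Genes of the sex-linked, reporter-locus, leukocyte and haemoglobin lists were given as checks whatever their values. Other list members in the text are examples chosen after their values were seen, as are the lists described at length.

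Free RNA (transcripts from burst cells that enter droplets) was estimated per cell type from markers of foreign lineages, scaled to the mean profile of the library. The estimate was 16.4% of UMIs in donor-library and 3.31% in recipient-library general capillary-like cells, 5.83% and 2.33% in aerocyte-like cells, 12.6% and 5.54% in venous-like cells, 4.50% and 2.49% in type 1-like cells, and 12.1% and 8.17% in pericyte-like cells. The donor-library estimates in endothelial types rest on 9 markers. The median gene differed between the libraries by a log2 ratio over 0.1 in type 1-like cells alone, where it was 0.12.

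The ratio code was tested on simulated data, Poisson counts for the real genes and depths with 50 genes changed at each size. Such counts follow the error model that the intervals assume and lack the clumping of UMIs in few cells. They check the code and do not give error rates for the real data. Of unchanged genes at 50 CPM or more, 0 of 3308 passed the size rule in general capillary-like cells, 0 of 3109 in aerocyte-like, 0 of 3149 in venous-like, 0 of 3033 in type 1-like and 2 of 3318 in pericyte-like cells. In the same order, the rule took 0%, 0%, 4%, 2% and 2% of genes changed 1.5-fold, 46%, 40%, 44%, 38% and 24% of those changed 2-fold, 100%, 100%, 98%, 96% and 94% at 3-fold, and 100%, 100%, 100%, 100% and 98% at 4-fold. The intervals held the true ratio for 95.4%, 95.1%, 95.97%, 95.3% and 95.8% of unchanged genes. Simulated lists changed 2-fold gave medians of 1.002, 0.99, 1.004, 1.18 and 0.88.

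The alternative settings for shares were fixed filter limits (at least 500 genes, mitochondrial share under 20%), no cell filter, doublets kept, no integration, resolutions of 0.5 and 2, and 3000 variable genes with 50 components. For ratios they were fixed limits, doublets kept, no integration, median-of-ratios scaling, the mean of per-cell CPM, equal weight for the clusters of a type and free RNA subtracted. For list medians they also included a member minimum of 100 counts and a minimum of 1 count in each library. Removal of barcodes present in both libraries was added after seeing the data. Both copies were removed where the smaller had over 0.2 of the UMIs of the larger, and otherwise the smaller copy. Clustering with another random seed was also added after seeing the data, because an earlier run of the same code, whose integrated values differed only by rounding in linear algebra, drew the border between alveolar and adventitial fibroblast-like cells elsewhere. The number of threads and the processor type of that library were then fixed, and repeated runs gave identical values. Sums and intervals were computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.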

Results

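Lung cells of C57Bl mice were profiled by droplet single-cell RNA sequencing 6 months after the mice had received a suspension of lung cells from donors carrying the red reporter tdTomato. Cells of 3 chimeric lungs were pooled and sorted as CD45-negative (non-leukocyte) cells with the reporter, which gave the donor library, and without it, which gave the recipient library. Each group therefore held 1 library and no replicate, so no test between the groups was possible and all intervals given are 95% intervals that cover counting error only. The donor library held 6319 cell barcodes with 37997269 UMIs (unique molecular identifiers, each a counted transcript), a median of 5433 UMIs per barcode and a range of 500 to 95986. The recipient library held 3784 barcodes with 26201315 UMIs, a median of 6056.5 and a range of 505 to 33949. After filtering, 4703 donor-library cells with 31845212 UMIs and 3209 recipient-library cells with 23477626 UMIs were left. The series description names donor-derived epithelial and endothelial clusters, and the comparisons ask which cell types the sorted donor cells comprised and how their transcripts differed from those of recipient cells of the same type. The type names were rebuilt here from marker genes fixed beforehand, and each name means a cluster like that type.

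Endothelial-like cells made up most of the donor library, whereas mesenchymal-like cells were the largest part of the recipient library. Endothelial-like cells were 4264 of 4703 donor-library cells, 90.7% (exact binomial interval 89.8 to 91.5), and 1243 of 3209 recipient-library cells, 38.7% (37.0 to 40.5). Mesenchymal-like cells were 2.19% (1.79 to 2.65) of the donor library and 52.6% (50.9 to 54.4) of the recipient library. Epithelial-like cells were 3.27% (2.78 to 3.82) and 7.01% (6.15 to 7.95). The cell filter lowered the donor-library shares of mesenchymal-like and epithelial-like cells and raised that of endothelial-like cells. Without it, endothelial-like cells were 74.5% of the donor library and 35.9% of the recipient library. Mesenchymal-like cells were then 11.3% and 48.2%, and epithelial-like cells 7.47% and 9.02%. These values include barcodes present in both libraries, described below. The CD45 and tdTomato gates and the dissociation set these shares, which are shares of sorted cells and not of the lung. Blood-like cells (red cells or platelets) were 0.574% and 0.312%, and unnamed clusters took 3.30% (2.80 to 3.85) and 1.31% (0.945 to 1.77). The limit on marker score that left 1 of the unnamed clusters (best match arterial endothelium, 23 donor-library and 11 recipient-library cells) without a name was set after the clusters had been seen.

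General capillary-like cells, the capillary type that renews itself and other capillary cells, were the largest donor type with 2416 cells, 51.4% (49.9 to 52.8), against 419 cells, 13.1% (11.9 to 14.3), in the recipient library. Aerocyte-like cells, the large capillary cells specialised for gas exchange, were 31.9% (30.5 to 33.2) of the donor library and 19.2% (17.8 to 20.6) of the recipient library. Among endothelial-like cells alone, general capillary-like cells were 56.7% (55.2 to 58.2) in the donor library and 33.7% (31.1 to 36.4) in the recipient library, and aerocyte-like cells were 35.1% (33.7 to 36.6) and 49.5% (46.7 to 52.3). Venous-like cells were 3.74% (3.22 to 4.32) and 3.09% (2.51 to 3.74) of all cells, and arterial-like cells 3.57% (3.06 to 4.14) and 1.15% (0.813 to 1.59). The arterial-like share of the donor library was 1.74% at resolution 2. With 3000 variable genes and 50 components, the arterial-like shares were 1.40% and 0.623%. Lymphatic-like cells numbered 6 in the donor library, 0.128% (0.0468 to 0.277), and 73 in the recipient library, 2.27% (1.79 to 2.85). Without integration of the libraries, only 2.93% of recipient-library cells fell into general capillary-like clusters, so this share and the values within the type depend on how the libraries were aligned.

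Alveolar type 1-like cells, the flat epithelial cells of gas exchange, were 129 donor-library cells, 2.74% (2.30 to 3.25), and 193 recipient-library cells, 6.01% (5.22 to 6.89). Alveolar type 2-like cells, which make surfactant, numbered 14 and 25, and ciliated-like cells 11 and 7. No cluster carried a club cell name in either library. Of the donor-library epithelial cells, 77 of the type 1-like, 7 of the type 2-like and 6 of the ciliated-like ones carried a barcode that also occurred in the recipient library, mostly with far more UMIs there. Without such barcodes the donor-library share of epithelial-like cells was 1.40% and that of type 1-like cells 1.14% (52 cells, 0.851 to 1.49). Other settings raised the donor-library share of type 1-like cells. It was 5.27% under fixed filter limits, 6.13% without a cell filter and 4.23% with doublets kept. None of these settings removed barcodes for being shared. Before any filter the donor copy was the smaller by over 5-fold in 728 barcodes, whereas 132 shared barcodes were left among the donor-library cells used here. How far such copies raised these shares was not tested. Pericyte-like cells were 1.25% of the donor library and 17.0% of the recipient library. Their donor-library share was 2.04% under fixed filter limits and 2.78% without a cell filter. Alveolar fibroblast-like cells were 0.510% and 24.2%, adventitial fibroblast-like cells 0.213% and 5.02%, myofibroblast-like cells 0.0638% and 5.48%, and smooth muscle-like cells 0.149% and 0.966%. The split between the first 2 of these depended on the clustering, since another random seed gave recipient shares of 19.7% for alveolar and 9.54% for adventitial fibroblast-like cells. Of the donor-library cells, 14 of 24 alveolar, 7 of 10 adventitial and 2 of 3 myofibroblast-like ones carried a barcode also present in the recipient library. Without them the donor-library shares were 0.219%, 0.0656% and 0.0219%. Under fixed filter limits the donor-library shares were 1.43% for alveolar and 1.62% for adventitial fibroblast-like cells. Without a cell filter they were 4.85% and 2.67%. Neither setting removed barcodes for being shared.

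**Figure D1:**
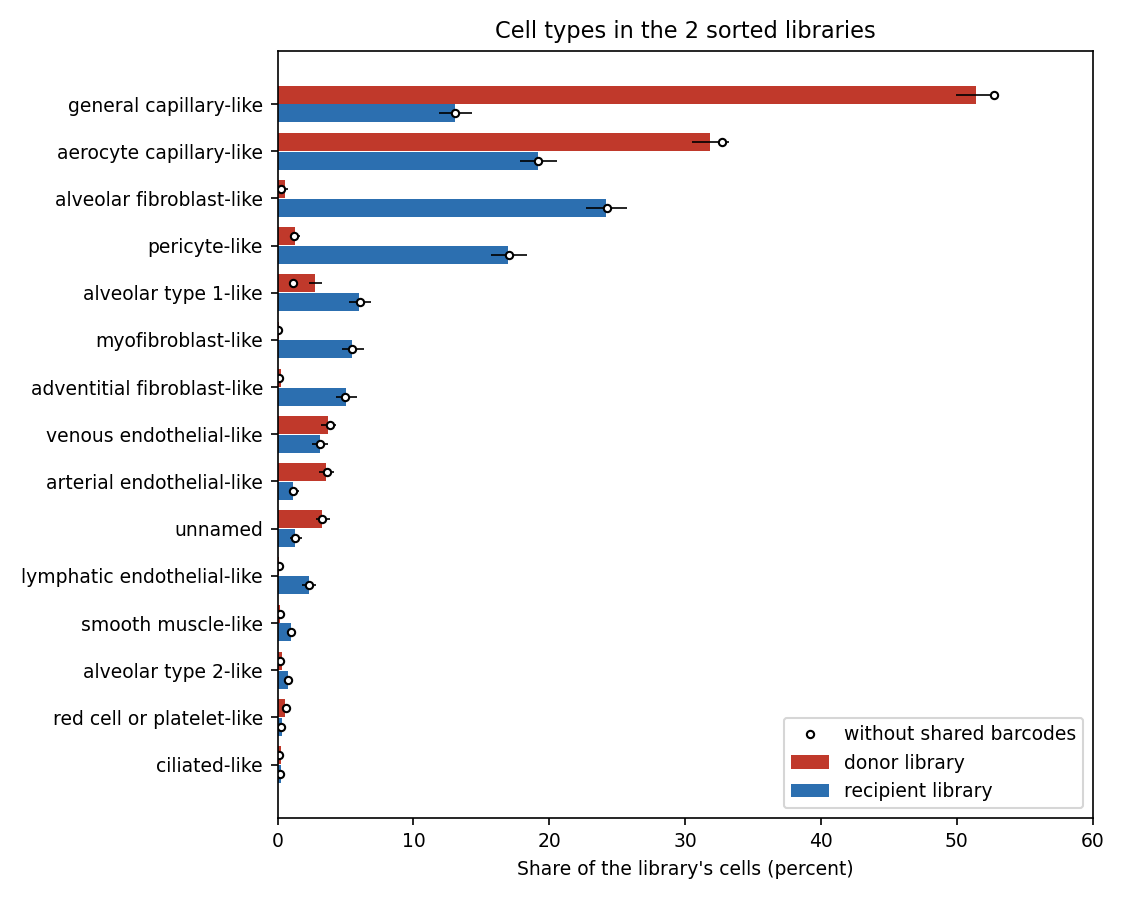
Share of the cells of each library (percent) in each cell type named here, with donor bars in red, recipient bars in blue, exact 95% binomial intervals as lines and the share without shared barcodes as open circles. General capillary-like cells stood at 51.4% in the donor library and 13.1% in the recipient library, and alveolar type 1-like cells at 2.74% and 6.01%.

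**Figure D2:**
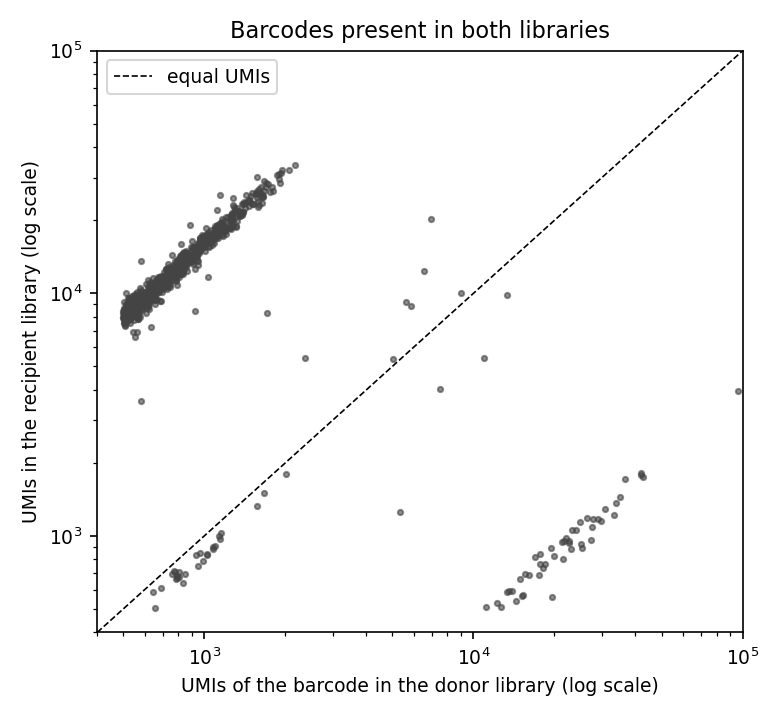
UMIs of each of the 816 barcodes present in both libraries, in the donor library against the recipient library (both axes log-scaled, dashed line for equal counts). The donor copy was the smaller by over 5-fold in 728 of them, with a median of 6.26% of the recipient copy's UMIs.

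In general capillary-like cells the donor library held more transcripts of Wif1, Sox11 and Tmem221, and the recipient library more of Ifi204 and Gdf15. Wif1, a secreted inhibitor of Wnt signalling, was at 76.4 CPM (counts scaled by the summed UMIs of the type) in the donor library and 3.73 in the recipient library, 20.5-fold higher (10.7 to 44.9). Sox11, a developmental transcription factor, was at 281 and 19.5 CPM, 14.4-fold higher (10.8 to 19.7). Gdf15, a stress-induced cytokine and p53 target, was at 31.4 and 206 CPM, 6.58-fold lower in the donor library (5.77 to 7.51). The 2 sums held 13581846 UMIs from 2416 donor-library cells and 2412021 UMIs from 419 recipient-library cells. Sox11 and Cd74 were among the genes that lead 1 of the 4 general capillary-like clusters and Grp leads another, so their ratios are not independent of the clustering. With equal weight for the clusters, the log2 ratio was 4.21 for Sox11 and 1.98 for Grp.

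Ifi208 and Ifi204, neighbouring genes of the interferon-inducible PYHIN family on chromosome 1, differed in opposite directions in these cells. Ifi208 (ENSMUSG00000066677, mm10, chromosome 1, 173673675 to 173698395) was 16.2-fold higher in the donor library (8.48 to 35.5), with 60.4 against 3.73 CPM. Ifi204 (ENSMUSG00000073489, chromosome 1, 173747293 to 173766943) was 10.7-fold lower (9.52 to 12.1), with 31.2 against 335 CPM. The labels give C57Bl for the recipients and no strain for the donors, so a difference of strain is not excluded for these genes. Among the genes that met the naming rule, the largest donor-higher ratio was that of Tmem221 (ENSMUSG00000043664, chromosome 8, 71554238 to 71558871), 33.2-fold (14.2 to 103), with 68.9 against 2.07 CPM and only 5 recipient UMIs. Wif1 (ENSMUSG00000020218) lies on chromosome 10 from 121033960 to 121100650, Sox11 (ENSMUSG00000063632) on chromosome 12 from 27334264 to 27342574 and Gdf15 (ENSMUSG00000038508) on chromosome 8 from 70629393 to 70632456. The other donor-higher genes given here lay between log2 ratios of 2.06 and 3.16. They were Casc4 at 178 and 19.9 CPM, the securin gene Pttg1 at 87.1 and 17.0, Cd24a at 180 and 41.9, the peptide gene Grp at 63.9 and 15.3, and the tetraspanin Tspan8 at 353 and 84.6. Those higher in the recipient library lay between −2.71 and −1.60. They were the tRNA deaminase gene Adat1 at 8.17 and 53.5 CPM, the glutathione transferase Mgst1 at 18.0 and 97.4, Clec1b at 15.6 and 59.3, Plac8 at 82.5 and 306, Gbp8 at 19.1 and 67.2, Spata7 at 22.8 and 75.04, the death receptor Tnfrsf10b at 21.8 and 68.4, and the protease inhibitor Serpina3g at 32.5 and 98.7. For Spata7, 103 of the 181 recipient UMIs came from 3 cells. Without integration the log2 ratio of Grp was 0.19, that of Gbp8 −0.64, that of Serpina3g −1.04, that of Ifi204 −4.17 and that of Plac8 −2.60. With free RNA subtracted, that of Clec1b was −4.72, that of Ifi204 −4.24 and that of Gdf15 −3.998.

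**Figure D3:**
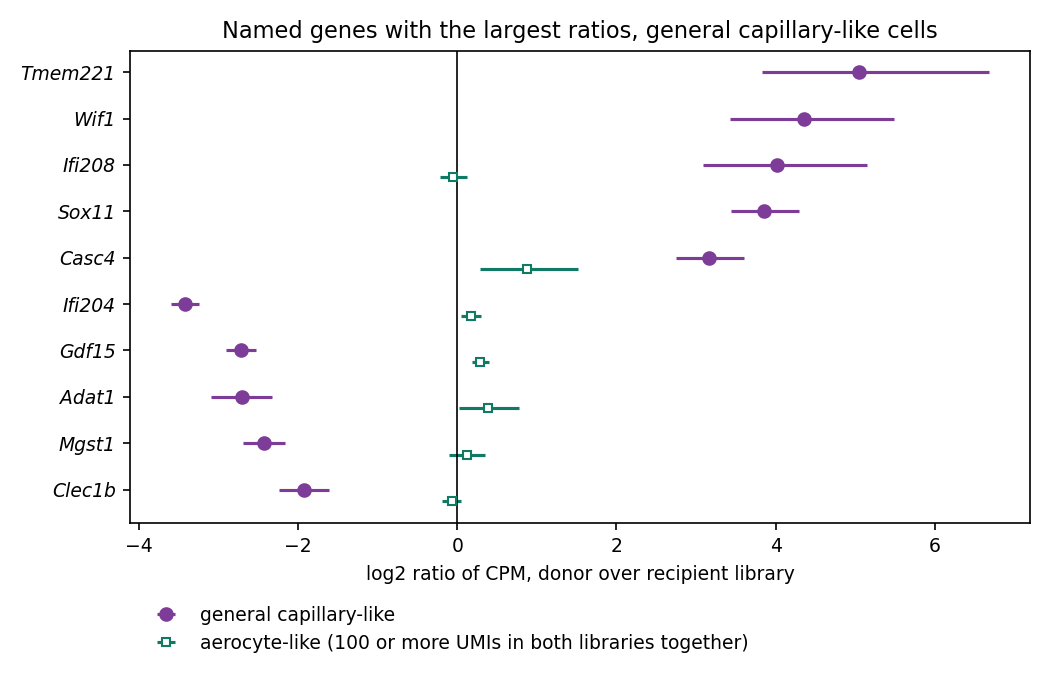
Log2 ratio of donor over recipient CPM for the named genes with the 5 largest ratios each way in general capillary-like cells (purple points, 95% counting intervals) and, where they held at least 100 UMIs, for the same genes in aerocyte-like cells (squares). Tmem221 stood at 5.06 and Ifi204 at −3.42 in general capillary-like cells.

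MHC class II genes, which present antigen to helper T cells, were higher in donor-library general capillary-like cells with a median log2 ratio of 0.55 (0.45 to 0.64) over 7 measured members. That median stood at percentile 100 among random lists matched on expression. Cd74 was at 3177 and 2021 CPM, H2-Ab1 at 889 and 672, and the class II transactivator Ciita at 40.9 and 23.2, and 3 members were at least 1.5-fold higher. The interferon response list had a median of 0.13 (0.081 to 0.17) over 33 members (percentile 99.9), with Bst2 at 1153 and 728 CPM and Ifi27l2a at 15.6 and 46.0. Without integration the interferon median was −0.0040.

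Lists of p53 targets, senescence, inflammation and TGF-beta response were lower in the donor library in the same cells. The p53 target list had a median of −0.42 (−0.52 to −0.25) over 22 members (percentile 0), with 8 members at least 1.5-fold lower and 2 higher. Its members included Gdf15, Tnfrsf10b, Eda2r at 1.62 and 11.6 CPM, Phlda3 at 113 and 220 and the apoptosis gene Bax at 150 and 241, whereas Pmaip1 was at 68.2 and 39.0 and Plk2 at 700 and 532. The senescence and secretory list had a median of −0.48 over 16 members, although the cell cycle inhibitors Cdkn2a (41.2 and 19.1 CPM) and Cdkn2b (27.9 and 16.2) were higher in the donor library. The inflammatory list had a median of −0.40 over 16 members, with the adhesion gene Vcam1 at 18.6 and 126 CPM, and stood at −0.20 over members with at least 100 counts and −0.71 with a minimum of 1 count in each library. The TGF-beta list had a median of −0.40 over 20 members, with Bambi at 54.7 and 92.0 CPM. Col1a1 (0.515 and 13.3 CPM) and Col3a1 (0.295 and 15.3), which fibroblasts make, moved with that list, and its median was −0.65 with doublets kept, 0.084 with free RNA subtracted and 0.0082 over members with at least 100 counts.

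Lipoprotein lipase (Lpl) was 3.09-fold higher in donor-library general capillary-like cells, at 366 and 118 CPM, and the fatty acid carrier Fabp5 2.81-fold lower, at 31.6 and 88.7. The list of endothelial lipid and barrier genes as a whole had a median of 0.026. The general capillary genes Gpihbp1 (2407 and 2303 CPM) and Plvap (3761 and 3488) were nearly level. The stem cell and endothelial surface gene Cd34 was at 63.5 and 133 CPM and Cd200 at 531 and 276. The cell cycle list had a median of −2.70 over 20 members, but 318 of the 338 UMIs of proliferation markers in recipient-library general capillary-like cells came from 2 cells, and the median was −0.057 over members with at least 100 counts. Lists of alveolar type 1 (−1.86) and surfactant genes (−0.90), which mainly hold epithelial genes, were also lower in the donor library, at levels such as 15.2 and 64.7 CPM for Ager. The type 1 list also holds Emp2, an aerocyte marker here, and Cav1, a member of the endothelial lipid and barrier list. The type 1 median was 0.014 over members with at least 100 counts, and the surfactant median 0.23 with free RNA subtracted and −1.93 without integration.

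In aerocyte-like cells the 2 libraries were much closer, and no gene met all parts of the naming rule. The matrices hold no feature for tdTomato, so recipient cells that entered the donor gate would have been counted as donor cells. The MHC class II list had a median of 1.75 (1.26 to 1.98) over 7 members (percentile 100), yet its levels were low, with Cd74 at 60.3 and 16.3 CPM and H2-Ab1 at 18.7 and 5.42. General capillary genes at similarly low levels were higher in the donor library too, with Plvap at 72.2 and 21.9 CPM and Lpl at 6.05 and 1.73. Early response genes, which cell dissociation and stress switch on, had a median of 0.29 over 26 members (percentile 100), none at least 1.5-fold apart, with Atf3 at 521 and 355 CPM and Junb at 2189 and 1568. The p53 target list had a median of 0.0020, with Gdf15 at 230 and 188 CPM, in contrast to general capillary-like cells. TGF-beta response genes had a median of −0.59 (percentile 0), again with fibroblast genes such as Col3a1 at 0.443 and 9.32 CPM, and 0.011 over members with at least 100 counts. The aerocyte genes Kdr (1962 and 2177 CPM), Ednrb (1471 and 1686) and Apln (480 and 486) differed little. The sums held 13557865 UMIs from 1498 cells and 4614577 UMIs from 615 cells, and with doublets kept the class II median was 2.52.

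Venous-like cells of the donor library held more MHC class II, interferon and angiogenesis transcripts and fewer adhesion transcripts. All 7 measured class II members were at least 1.5-fold higher, with a median log2 ratio of 1.42 (1.31 to 1.74) and Cd74 at 2247 and 478 CPM, H2-Aa at 519 and 167, H2-Eb1 at 516 and 163, H2-Ab1 at 570 and 218 and H2-DMa at 143 and 53.3. The interferon list had a median of 0.35 over 31 members (percentile 100), with 8 higher, among them Ifit1 at 132 and 67.5 CPM, Ifit3 at 144 and 65.1 and Zbp1 at 49.97 and 15.4. The chemokine Cxcl10 went the other way, at 57.2 and 295 CPM. The inflammatory and adhesion list had a median of −0.55 over 13 members (percentile 0), with P-selectin (Selp) at 187 and 603 CPM and Vcam1 at 587 and 1531. The angiogenesis list had a median of 0.33 over 21 members (percentile 99.9), with Pdgfb at 233 and 82.9 CPM and Dll4 at 38.1 and 10.7, whereas Nrp2 was at 86.1 and 228.

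Of single genes in the venous-like cells, Rgs5 was seen in the donor library alone. It had 170 donor UMIs, 112 CPM (95.6 to 130), and 0 in the recipient library. With a floor of 3 counts over the group in place of 0 it was 31.5-fold higher, and the lower limit of its interval was 25.3-fold. Sox11 was 14.996-fold higher (7.77 to 33.2), at 160 and 10.7 CPM, and Pttg1 7.38-fold higher (3.44 to 18.9). Other list members that met the naming rule were Clu at 223 and 68.7 CPM and the hypoxia-induced Ankrd37 at 53.9 and 11.8. Those lower in the donor library were Hspg2 at 11.8 and 73.4 CPM, Mgp at 227 and 985, Bgn at 332 and 798, Cd34 at 112 and 226, Ctsh at 249 and 636, Tnfrsf10b at 29.6 and 93.5, Egr3 at 58.5 and 134, Cyp1a1 at 36.8 and 82.9 and Aldh1a1 at 71.7 and 147. Among genes that met the naming rule, the largest ratios in that direction were those of Mfap4, with 2 donor UMIs and 48 recipient UMIs (43.2-fold, 11.3 to 367), Mt1 at 2.63 and 88.8 CPM and Fbln2 at 5.92 and 55.6. Few cells set the last 2, since 64 of 75 Mt1 UMIs and 46 of 47 Fbln2 UMIs came from 3 recipient cells, and Fbln2 turned to a log2 ratio of 1.58 under fixed filter limits and 1.16 with doublets kept and was −1.92 without integration. Mfap4 is one of the mesenchymal markers and was among the 10 leading genes of an alveolar fibroblast-like cluster. The level part of the naming rule covered only the 5 compared types, none of them fibroblast-like. Free RNA of fibroblast-like cells was therefore not screened out for Mfap4. The class rested on 176 and 99 cells.

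In alveolar type 1-like cells the epithelial genes were close in both libraries, with Ager at 17387 and 18425 CPM and Hopx at 14069 and 14282. Of the 129 donor cells, 77 carried a barcode also present in the recipient library, so the 2 sums are not fully independent. With shared barcodes removed, Ager stood at 16021 and 18425 CPM. The growth factor Vegfa was at 2459 and 3669 CPM. Basement membrane genes had a median of −0.39 over 18 members (percentile 0), with the collagen gene Col4a3 at 651 and 871 CPM, and −0.22 with equal weight for the clusters and −0.60 with doublets kept. The type 1 program had a median of −0.13 over 14 members. It was 0.11 with equal weight for the clusters, −0.19 with shared barcodes removed and −0.55 with doublets kept. Different clusters held these cells in the 2 groups. Cluster 14 held 145 of the recipient cells and 14 donor cells, cluster 17 held 72 donor cells, 64 of them with a shared barcode, and 13 recipient cells, and cluster 19, which immune genes also marked, held 43 and 35. Median depth was 1462 UMIs in the donor cells and 14268 in the recipient cells.

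Immune and endothelial transcripts set the donor type 1-like cells apart from the recipient ones. The MHC class II list had a median of 2.98 (2.88 to 3.48) over 7 members, the leukocyte list 2.27 over 11, the interferon list 0.67 over 25 and the endothelial barrier list 1.28 over 18, each at percentile 100. Cd74 was at 2351 and 299 CPM, the macrophage lysozyme Lyz2 at 2738 and 143, Tyrobp at 174 and 29.6, Isg15 at 262 and 62.8 and Cldn5 at 179 and 31.8. The other class II genes that met the naming rule were H2-Aa at 762 and 33.6 CPM, H2-Ab1 at 740 and 26.2, H2-Eb1 at 637 and 18.5, H2-DMa at 71.02 and 9.97, H2-DMb1 at 105 and 28.4 and Ctss at 122 and 24.7. Of leukocyte and interferon genes, Fcer1g was at 164 and 24.4 CPM, Cd52 at 78.4 and 16.3, Coro1a at 58.8 and 15.9 and Ifi27l2a at 135 and 6.28. A few donor cells set these values, since 830 of 960 Cd74 UMIs and 1029 of 1118 Lyz2 UMIs came from 3 cells. The leukocyte median was 0.51 when each cell counted equally, 0.94 with equal weight for the clusters, 2.70 with shared barcodes removed, 3.33 under fixed filter limits and 4.01 without integration. The interferon median was 0.17 when each cell counted equally, 0.95 with shared barcodes removed, 1.19 under fixed filter limits and 1.21 with doublets kept. The barrier median turned to −0.083 with free RNA subtracted and was 3.497 without integration.

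The genes named by size in type 1-like cells also came from a few cells. The platelet genes Ppbp (184 and 0 CPM, 166-fold higher with the floor, lower limit 131) and Pf4 (216 and 4.43 CPM) had 74 of 75 and 86 of 88 donor UMIs in 3 cells, as had Clec1b, with 22 of 23 donor UMIs and 1 recipient UMI (152-fold, 24.8 to 6281). The club cell genes Scgb1a1 (26.9 and 9064 CPM) and Scgb3a2 (0 and 501 CPM, 68.1-fold lower in the donor library with the floor, lower limit 55.3) and Retnla (2.45 and 385 CPM) had 24318 of 24536, 1347 of 1355 and 1037 of 1041 recipient UMIs in 3 cells. The surfactant gene Sftpc was at 698 and 279 CPM, whereas Sftpa1 was at 14.7 and 89.03 and Cbr2 at 9.80 and 87.2. Retnla turned to a log2 ratio of 0.43 without integration, where Scgb1a1 stood at −1.75, against −10.5 with equal weight for the clusters, and Pf4 was at 3.89 when each cell counted equally.

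Pericyte-like cells, which wrap capillaries, held more MHC class I and class II transcripts in the donor library, from 59 cells against 545. The class II list had a median of 3.29 (2.496 to 4.07) over 5 members, with Cd74 at 178 and 10.0 CPM and H2-Ab1 at 77.1 and 4.01, and the class I list 0.33 over 16 members, with H2-K1 at 970 and 618. Of the 60 donor UMIs of Cd74, 41 came from 3 cells, and 18 of the 59 cells had any. The endothelial genes Gpihbp1 (131 and 26.7 CPM) and Plvap (208 and 28.7) were higher in the same cells, and the endothelial barrier list had a median of 0.38. With free RNA subtracted, the class I median was −0.11 and the barrier median −0.22, and with doublets kept they were 0.87 and 1.43. The contractile gene Acta2 was at 246 and 47.1 CPM (5.23-fold, 3.94 to 6.90), with 63 of 83 donor UMIs in 3 cells, and the long non-coding RNA gene Snhg18 at 71.2 and 21.4. The interferon-induced Igtp was at 50.4 and 15.7 CPM and Thbs1 at 59.3 and 22.1. All 31 donor UMIs of Dlk1 came from 1 cell, against 0 in the recipient library. With doublets kept, the log2 ratio was 0.23 for Acta2 and 0.33 for Snhg18, and without integration that of Acta2 was 3.94.

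**Figure D4:**
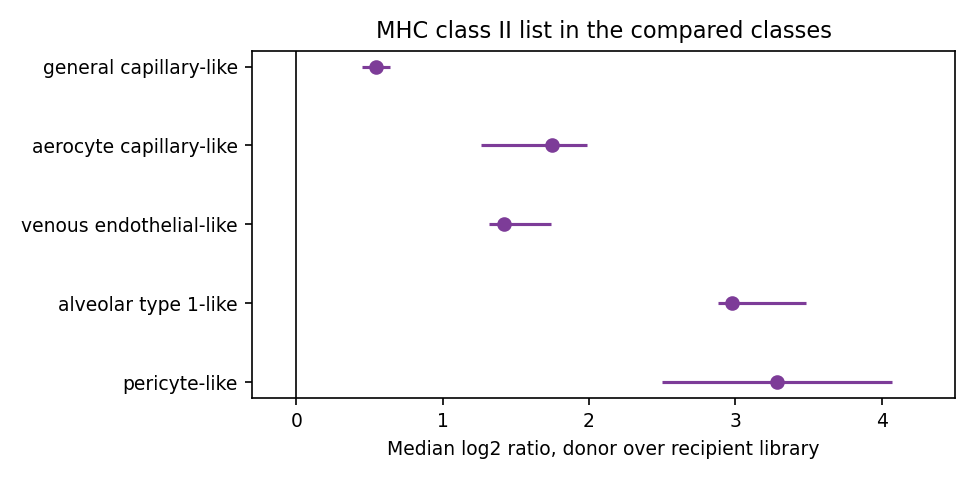
Median log2 ratio of donor over recipient CPM for the MHC class II list in the 5 compared cell types, with 95% intervals from redrawn counts. The medians ran from 0.55 in general capillary-like cells to 3.29 in pericyte-like cells.

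Across the 5 compared types, Cd74 was the gene 2-fold higher in the donor library in at least 4, with a median log2 ratio of 2.23 and general capillary-like cells as the exception. In venous-like cells 152 of 176 donor cells held it. In type 1-like and pericyte-like cells, 3 cells held 830 of 960 and 41 of 60 donor UMIs. In aerocyte-like cells it stood at 60.3 and 16.3 CPM, a level that free RNA may account for. Scgb1a1 and Mgp were 2-fold lower in all 5, with medians of −5.08 and −4.97. The levels of Scgb1a1 were 3.24 and 124 CPM in general capillary-like cells and 2.80 and 94.9 in aerocyte-like cells, far under the recipient type 1-like cells that held most of it. Mgp stood at 3.90 and 122 CPM in general capillary-like cells, against 24173 in recipient adventitial fibroblast-like cells.

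Over all cells of a library, Xist, the transcript of the inactive X chromosome of females, had 3358 UMIs in the donor library and 19 in the recipient library, 105 and 0.809 CPM. The Y-linked Ddx3y was at 110 and 109 CPM and Eif2s3y at 64.97 and 80.03. The transcript of the Rosa26 locus, Gt(ROSA)26Sor, was at 38.2 and 45.8 CPM, and its neighbour Setd5 at 109 and 81.4, while its neighbour Thumpd3 had a log2 ratio of −0.019. Further sex-linked and strain-variable genes had log2 ratios of 0.54 (Tsix) and −0.24 (Uty) and, with intervals that included 0, −0.086 (Kdm5d), −0.015 (Wdfy1), −0.020 (Glo1), 0.084 (Ide) and 0.15 (Gbp2b), and Entpd4 had no UMIs. The leukocyte gene Ptprc, which encodes CD45, was at 0.722 and 1.79 CPM, a log2 ratio of −1.31. Lower in the donor library were also Csf1r (−2.66, 3.39 and 21.4 CPM), S100a9 (−2.39), Rac2 (−1.76), Coro1a (−1.71), Laptm5 (−0.87), Tyrobp (−0.70), Cd52 (−0.66) and Lyz2 (−0.24). Cd74 (2.08) and Srgn (1.29), also expressed outside leukocytes, were higher. The intervals of S100a8 (−0.73, −2.18 to 0.68), Cd79a (−0.44, −2.86 to 1.98), Fcer1g (−0.14, −0.53 to 0.26) and Cd3e (2.37, −0.59 to 7.86) included 0. The red cell gene Hbb-bs was at 4.15 and 2.60 CPM, with log2 ratios of 0.85 for Hba-a1, 0.88 (−0.91 to 3.01) for Hba-a2 and 0.66 (−0.72 to 2.20) for Hbb-bt, 2 and 0 UMIs of Hbb-bh1 and 1 each of Alas2. Mitochondrial genes lay between −0.51 (mt-Nd6) and 0.22 (mt-Nd3), with mt-Co1 at 3248 and 3807 CPM.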

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

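The test of a fixed rate of index exchange was written before its result was seen, and the tests of chance meeting and of the differences missing from aerocyte-like cells were chosen after.

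Of all barcodes, 816 occurred in both libraries, a signal outside the measured comparisons, and the smaller copy held under 0.2 of the UMIs of the larger in 95.1% of them. Chance meeting of unrelated barcodes is excluded as the cause, since random pairing gave 19.0% and at most 22.9% in 100 draws. The donor copy was the smaller in 728 barcodes, at a median of 6.26% of the recipient's UMIs (middle 80% of barcodes 5.80 to 6.75), and the recipient copy in 48, at 4.21%, and profiles of true pairs correlated at 0.564 across genes (genes are not independent replicates) against 0.268 for shuffled pairs. Molecules of one library read under the index of the other at a fixed rate may account for them, as 83.3% of recipient barcodes deep enough to leave a donor copy had one (324 of 389), but 8.59% of those too shallow had one too (78 of 908), above the limit of 5% set in advance, so this stays open. Of those 78, 48 were themselves the smaller copy of a donor barcode and 29 had a ratio over 0.2, and no biological explanation was tested.

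Xist, which has no place in a comparison of the groups, was found in 478 of 4571 donor-library cells after removal of shared barcodes (10.5%), above the 16 of 3192 recipient-library cells (0.501%), and the cells with it were unevenly spread over types. Thinned to 2000 UMIs per cell, it was found in 14.2% of donor-library general capillary-like cells (12.9 to 15.7, 341 of 2397, 15 shallower cells left out), 17.0% of arterial-like and 12.7% of venous-like cells, but 0.335% of aerocyte-like cells (0.109 to 0.780, 5 of 1492, 4 left out). Thinned donor-library pericyte-like and type 1-like cells gave none, 0 of 54 (upper limit 6.60%) and 0 of 27 (upper limit 12.8%). Unthinned shares in general capillary-like and aerocyte-like cells were 16.5% (397 of 2412) and 1.34% (20 of 1496), at median depths of 5330.5 and 8806 UMIs. In the recipient library, whose cells gave almost no Xist, it was found unthinned in 5.18% of alveolar type 1-like cells (2.51 to 9.32, 10 of 193, and 1 of 182 thinned), in 0.240% of general capillary-like cells and in 0 of 611 aerocyte-like cells, where the exact 95% upper limit for the share of cells with a detected Xist UMI is 0.602%. These shares count cells with any Xist UMI, and background UMIs were not measured for Xist, while a Y-linked UMI was also found in 9 of the 10 recipient type 1-like, 17 of the 20 donor-library aerocyte-like and 46 of the 397 donor-library general capillary-like cells with Xist.

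The differences between the libraries in general capillary-like cells were mostly missing from aerocyte-like cells, as 25 genes show that were picked in general capillary-like cells and had recipient levels within 2-fold of each other in the 2 types. Their median log2 ratio, signed by the direction in general capillary-like cells, was 1.74 there, 1.65 in venous-like and 1.41 in arterial-like cells. It was 0.22 in aerocyte-like cells and also low, without matched levels, in type 1-like (0.31, 21 genes) and pericyte-like cells (0.099, 23 genes). For genes lower in the donor library this argues against low expression in aerocytes as the whole cause. Gdf15, for example, stood at 230 and 184 CPM in aerocyte-like cells. For genes higher in the donor library it cannot tell, because genes were matched on recipient levels. In aerocyte-like cells 6 of the 25 were still 2-fold apart (Scgb1a1, Mgp, Gsn, Apoe, Spp1 and Ager). All 6 were lower in the donor library and had higher levels in other recipient-library types. Male sex of the donor animals by itself did not remove the differences in general capillary-like cells. There, 35 genes were picked in the 351 cells with Xist and no Y-linked UMI. Against recipient cells not used to pick them, their signed median was 1.41 (middle 50% of genes 0.83 to 2.27) in the 1373 with a Y-linked UMI and no Xist. In aerocyte-like cells it was 0.13. Whether the aerocyte-like cells came from male donor animals alone cannot be told, because only general capillary-like cells were split by sex. Another origin of the aerocyte-like cells of the donor library, such as recipient cells without the reporter that entered the donor gate, stays open, because the share of 0.335% with Xist prompted the idea and cannot support it. A response of some cell types to transplantation and differences between the pooled animals also stay open, as untested.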

How the results depend on the processing

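No paired analysis was possible because each group held 1 library, and with no replicate there was no test whose outcome could change, so a value was taken as moved when it left its own 95% counting interval. Of 248 recomputed shares 180 stayed within it and 68 moved, of 629 list medians 511 stayed, 92 moved and 26 changed sign, and of 267 ratios of named genes 240 stayed, 24 moved and 3 changed sign. No share moved at resolution 0.5. The rarer types rested on fewer cells and UMIs, and the cause was not tested for the changes listed except where the setting itself names it.

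Under fixed filter limits the donor-library shares were 82.4% endothelial, 6.46% epithelial and 5.35% mesenchymal and the recipient epithelial share 8.18%, the MHC class II median of type 1-like cells was 2.74, and the early response median of pericyte-like cells (−0.083) and Fbln2 in venous-like cells (1.58) changed sign. Without a cell filter the donor-library shares were 74.5% endothelial, 7.47% epithelial and 11.3% mesenchymal, and the recipient shares 35.9%, 9.02% and 48.2%. Neither setting removed barcodes for being present in both libraries. With doublets kept the donor-library shares were 89.5% endothelial, 4.75% epithelial and 2.77% mesenchymal, the class II medians 2.52 in aerocyte-like and 2.62 in type 1-like cells, and Fbln2 changed sign (1.16). With 3000 variable genes and 50 components the donor endothelial share was 91.8% and the recipient mesenchymal share 50.9%, and at resolution 2 the recipient mesenchymal share was 47.6%. Without integration the endothelial shares were 88.3% and 27.8%, the general capillary medians were 0.71 for class II and −0.0040 for interferon, which changed sign, and Retnla in type 1-like cells changed sign (0.43). With shared barcodes removed, an alternative chosen after seeing the data, the donor-library shares were 93.1% endothelial and 1.40% epithelial, and 1.66% mesenchymal. With another random seed, also chosen after seeing the data, the recipient shares of alveolar (19.7%) and adventitial fibroblast-like cells (9.54%) moved and no other value did.

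The class II median of type 1-like cells was 2.86 with median-of-ratios scaling, 2.38 with the mean of per-cell CPM, 2.65 with equal weight for the clusters and 3.74 over members with at least 100 counts, and the p53 median of general capillary-like cells was −0.53 with a minimum of 1 count in each library. Medians that changed sign with free RNA subtracted were surfactant (0.23), transitional state (0.064) and TGF-beta (0.084) in general capillary-like cells, transitional state (0.12) and type 1 program (0.029) in aerocyte-like cells, barrier (−0.083) and progenitor (−0.028) in type 1-like cells, and type 1 program (−0.20), MHC class I (−0.11), barrier (−0.22) and progenitor (−0.11) in pericyte-like cells. With at least 100 counts per member they were type 1 program (0.014), xenobiotic metabolism (0.11) and TGF-beta (0.0082) in general capillary-like cells, transitional state (0.026) and TGF-beta (0.011) in aerocyte-like cells, lipid synthesis (0.080) and basement membrane (0.0096) in venous-like cells, and angiogenesis (−0.30) and progenitor (−0.13) in type 1-like cells. In type 1-like cells the type 1 program (0.11) and inflammatory list (−0.018) changed sign with equal weight for the clusters, and the inflammatory (−0.011) and progenitor lists (−0.099) with the mean of per-cell CPM.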

Other observations

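Venous-like cells differed in further lists. Notch pathway genes, which pattern arteries and sprouts, had a median log2 ratio of 0.30 over 11 members, with Hey1 at 41.4 CPM in the donor library and 17.8 in the recipient library and Notch4 at 92.7 and 48.5. MHC class I had a median of 0.26 over 17 members, none at least 1.5-fold apart (0.13 without integration and 0.18 when each cell counted equally), and lipid synthesis one of −0.28, which was 0.080 over members with at least 100 counts. Basement membrane genes had a median of −0.35, 0.0096 over such members, and the collagen gene Col4a1 was at 478 and 246 CPM. The tip cell gene Esm1 was at 25.6 CPM from 39 UMIs in the donor library and 2.37 from 2 UMIs in the recipient library, a log2 ratio of 3.44 (1.49 to 6.53).

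In general capillary-like cells many lists lay near 0, with heat shock at 0.0081, the unfolded protein response at −0.051, progenitor genes at −0.060, oxidative phosphorylation at 0.0046, mitochondrial-encoded genes at −0.0041, glycolysis at −0.0079, early response at −0.015, Wnt at −0.078, Notch at 0.079, angiogenesis at 0.068, MHC class I at −0.11 and antioxidant genes at −0.099. Among angiogenesis genes the donor library was nevertheless higher for Dll4 (358 and 238 CPM) and lower for the lymphatic growth factor Vegfc (40.4 and 83.3) and its co-receptor Nrp2 (11.6 and 45.2). Von Willebrand factor (Vwf) was at 628 and 437 CPM. The alveolar transitional list stood at −0.33 (0.064 with free RNA subtracted and −0.97 without integration), basement membrane at −0.31 (−0.17 with free RNA subtracted, −0.75 without integration and −0.90 with a minimum of 1 count in each library), xenobiotic metabolism at −0.28 (0.11 over members with at least 100 counts and −0.62 without integration) and lipid synthesis at −0.22 (−0.040 without integration).

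The tests of MHC class II were chosen after its medians had been seen. The class II list was higher in the donor library in all 5 compared types, by 0.55 in general capillary-like, 1.42 in venous-like and 1.75 in aerocyte-like cells. Free RNA of general capillary-like cells may account for the aerocyte value, as 9 general capillary markers that aerocytes lack were higher there by a median log2 ratio of 1.61, and the class II level in donor-library aerocyte-like cells was 0.964% of the highest level in any donor-library type. In general capillary-like and venous-like cells the class II levels were 46.6% and 33.1% of that of alveolar type 2-like cells. The latter were the highest type in the donor library, with 7 cells. Levels of that size argue against free RNA as the whole source of these transcripts. They do not test how much free RNA adds to the difference between the libraries. Donor-library type 1-like cells reached 49.3% by the same measure, although 3 cells held most of their Cd74 UMIs. Both libraries were sorted from the same pool of 3 chimeric lungs. A difference between donor and recipient endothelium, or between the donor animals and the recipient animals, stays open as untested.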
